A study of Brassica rapa subsp. pekinensis with 2 samples.

How the data were processed

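RNA sequencing of newly expanded leaves of Chinese cabbage (Brassica rapa ssp. pekinensis) compared 1 water-sprayed and 1 MeJA-sprayed (0.2 mM) sample, both taken 24 h after the spray. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, fragmented, copied with random hexamer primers and sequenced on an Illumina HiSeq instrument. The labels assign each library to its group by the spray. How many plants were pooled per library is not given in the sources used here.

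Per the file headers, the authors deposited for each gene a count of uniquely placed reads, the gene length, the percent of the gene covered by reads, RPKM, a protein match and gene ontology terms. The aligner, the counting tool and the genome build are not given in the sources used here. The deposited RPKM values equal reads divided by gene length and by the library's total for every gene, with a largest relative deviation of 5.1e-15. The totals, 4636699 for water and 4438684 for MeJA, equal the sums of the deposited counts. Gene lengths are multiples of 3 for 99.95% of genes, so they are taken as coding lengths. Genes without reads are not listed in a deposited table and were given 0 reads. At these depths 1 read on a gene of 1 kilobase is worth 0.216 RPKM in the water library and 0.225 RPKM in the MeJA library. The 20 most abundant genes took 16.9% and 16.3% of the reads. Counting unique reads leaves out those that fit near-identical copies, which are frequent in this genome, and strand use in counting is not stated.

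With 1 library per group there are no residual degrees of freedom, so no test between treatments was made. A log2 ratio is log2 of (MeJA RPKM + 0.1) over (water RPKM + 0.1), which understates the difference of low genes. Genes with at least 1 RPKM in the higher library were tested against a fixed size of 2-fold. Folds without pseudocount have a 95% exact (Clopper-Pearson) interval from the conditional binomial distribution of the reads, which covers counting error only and compares the libraries, not the conditions. A gene without reads in a library entered the log2 ratios, 2-fold counts and list medians at 0 RPKM plus 0.1. A floor of 3 reads was used only for medians and folds that are stated against it. List medians have an order-statistic 95% interval over members and a percentile among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of these libraries. The random lists were drawn from all tested genes, members of the list itself included.

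The 27 gene lists, the rule for named genes and the alternative settings listed first below were written before the data were examined. Members were found by protein name in the deposited annotation, in which 41.7% of genes have an uninformative match. After annotation and values had been seen, 110 matches to other proteins were removed (such as methionine enzymes matched by the word thionin), members under other spellings were added as an alternative, and 8 gene families were picked for the closing section. The lists cover JA biosynthesis, JA signalling, JA-responsive defence, indole and aliphatic glucosinolate synthesis, glucosinolate breakdown, tryptophan, phenylpropanoid, flavonoid and terpenoid synthesis, light harvesting, senescence, salicylate, ethylene, abscisate, cell division, glutathione transferases, ribosomal proteins, housekeeping genes and 8 cell-type marker sets. Named genes are the 5 highest and 5 lowest log2 ratios among genes with at least 10 RPKM, the 3 tested members farthest from 0 in each of 9 core lists, the 1 such member of each other list, and the highest-RPKM match to each of 7 jasmonate and salicylate markers. Other named genes were chosen after their values were seen. Gene ontology terms with 10 to 300 tested genes were ranked by median. A reference table for another genome assembly gave no usable link to the gene identifiers and was not used here.

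Alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), totals without the 20 most abundant genes of either library, pseudocounts of 0.01 and 1, no filter, at least 5 RPKM, at least 4-fold, an interval beyond 2-fold, names without hedging words, values summed per list member, and unmatched random lists. Those added after the data were seen are a median of all tested genes set to 0, a median of each of 10 coding length classes set to 0, random lists matched on coding length too, and the list changes above. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

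The calculation was tested on simulated counts for 22013 genes with 50 genes at each of 4 true folds. The 2-fold rule recovered 48 genes at 4-fold, with 1 other called in the wrong direction, 41 at 0.25-fold, 47 at 3-fold and 47 at 0.333-fold. The limit on wrong calls was relaxed after that gene was seen, and the reason for its call was not looked into. Intervals held the true fold for 96.1% of 20465 genes. Of 400 random lists drawn without a difference, 23 fell outside the central 95% of their matched lists; a first run with fewer lists was replaced by this larger one after its share had looked high.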

Results

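Transcripts of newly expanded Chinese cabbage leaves (cultivar ZSN5) were sequenced 24 h after a spray with pure water or with 0.2 mM methyl jasmonate (MeJA), the volatile ester of the defence hormone jasmonic acid (JA). Each treatment was represented by 1 library. The water library held 4636699 uniquely placed reads over 25710 genes and the MeJA library 4438684 reads over 26210 genes. In total 27461 genes had a read in either library and 24459 had reads in both. With no replicate in either group, no difference described here has a replicate check and no p-value was computed across genes. The words higher and lower compare these 2 libraries. The 95% intervals cover counting error alone, and are too narrow even for that if PCR copies of a molecule were counted as separate reads. Scaffold positions are those of the deposited tables, whose genome build is not given in the sources used here.

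The comparison of the MeJA library with the water library asked which leaf transcripts, among them those of secondary metabolism, differed a day after the hormone spray. In the MeJA library, 19 of 33 JA-responsive defence genes were at least 2-fold higher and 5 at least 2-fold lower. At least 2-fold higher were also 7 of 9 genes of JA synthesis, 3 of 4 of indole glucosinolate synthesis and 12 of 14 of glucosinolate breakdown. Of 367 ribosomal protein genes, 250 were at least 2-fold lower and 6 at least 2-fold higher. Among the 238 annotated as 40S, 60S or cytosolic, 200 were at least 2-fold lower. At least 2-fold lower were also 10 of 18 genes of cell division and 8 of 22 housekeeping genes. Genes of phenylpropanoid and flavonoid synthesis and of the light-harvesting complexes had medians close to 0 on the log2 scale. Of 22410 genes with at least 1 RPKM (reads per kilobase of gene, scaled to the library total) in the higher library, 3631 were at least 2-fold higher and 2434 at least 2-fold lower in the MeJA library on the deposited scale. The balance turned under TMM scaling (2751 higher, 3169 lower) and median-of-ratios scaling (2898 and 3006).

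**Figure D1:**
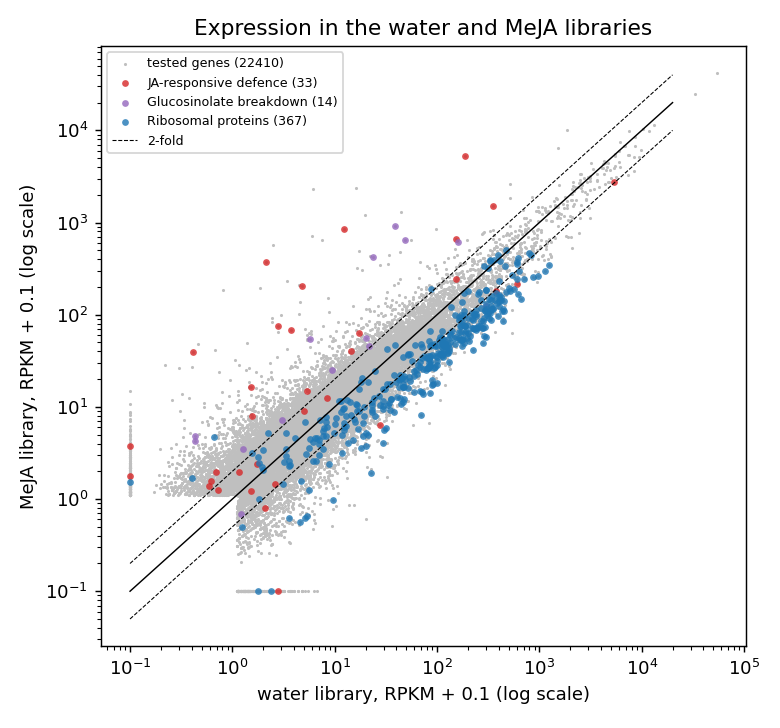
RPKM plus 0.1 of 22410 tested genes in the water library (x axis, log scale) and the MeJA library (y axis, log scale), with equality as a solid line and 2-fold differences as dashed lines. Most of the 367 ribosomal protein genes (blue) lie below equality, while 19 of 33 JA-responsive defence genes (red) and 12 of 14 glucosinolate breakdown genes (purple) lie at or above the upper 2-fold line.

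The gene with the largest log2 ratio among those with at least 10 RPKM was Bra027987, annotated as a GDSL-motif lipase/hydrolase, on Scaffold000058 from 1406611 to 1408549. It had 31 reads in the water library and 11443 in the MeJA library, a fold of 386 (interval 272 to 568). The interval of this gene overlaps those of the genes after it except Bra018969, so that most of their order is not resolved at this depth. Next came Bra010598, annotated as CYP81F4, a cytochrome P450 of indole glucosinolate modification (Scaffold000010, 2217851 to 2219730), with 5 and 1245 reads and a fold of 260 (111 to 802). The lipoxygenase gene Bra022535, annotated AtLOX2 (Scaffold000038, 427299 to 430928), was 238-fold higher (163 to 361). Bra008025, a Kunitz-type cysteine protease inhibitor, was 183-fold higher (83.9 to 501), and Bra018969, which the annotation leaves unnamed, was 149-fold higher (124 to 180). At the other end, where low read numbers leave the order open too, Bra031136, a hypothetical protein, had 83 reads in the water library and 2 in the MeJA library, 39.7-fold lower (10.7 to 333). Bra026173, a 10 kDa chaperonin that assists protein folding, was 19.8-fold lower (6.46 to 98.5). Bra016616, of unknown product, had 21 and 1 reads, and Bra006573, similar to a ripening-related protein, had 19 and 1. Bra024209, a hypothetical protein, was 12.7-fold lower (8.52 to 19.7).

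Genes that respond to JA in defence had a median log2 ratio of 1.49 over 33 tested members (interval over members 0.68 to 2.34). Of these, 19 were at least 2-fold higher, 5 at least 2-fold lower and 9 in between. The vegetative storage protein gene Bra020470, a standard marker of JA response, had 703 reads in the water library and 18746 in the MeJA library, 27.9-fold higher (25.8 to 30.1), and reached 5233 RPKM. A second Kunitz-type inhibitor gene, Bra008024, had 1 and 119 reads. The jacalin lectin gene Bra000129 was 69.3-fold higher (55.4 to 87.8). The abundant defensin-like gene Bra015809, the highest-expressed match to the PDF1.2 marker, went the other way, with 5321 RPKM in the water library and 2726 RPKM in the MeJA library, 1.95-fold lower (1.87 to 2.04). The list median lay above all 10000 random lists matched on mean expression, whose highest median was 0.76. With genes that had no read in 1 of the libraries set to 3 reads there, the median was 1.22. Matches to other proteins were removed from this list after its values had been seen, and with them left in the median was 0.37.

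Of the JA biosynthesis genes, 7 of 9 tested members were at least 2-fold higher and none was at least 2-fold lower, with a median log2 ratio of 1.99 (0.97 to 2.31). Of the genes for lipoxygenase 2, the plastid enzyme that starts JA synthesis, the 2 in the list were Bra004060, 3.98-fold higher (3.46 to 4.59), and Bra004059, 4.66-fold higher (3.58 to 6.12). The much larger fold of AtLOX2 (Bra022535), given above, is not in the list median because of its spelling. Bra004057 and Bra004058, annotated only as LOX and added after their values were seen, were 71.0-fold (52.2 to 99.1) and 3.04-fold (2.14 to 4.38) higher. The allene oxidase cyclase gene Bra017350, added likewise, was at 1.49-fold, with an interval that spans equality (0.717 to 3.19). Lipoxygenase 4 (Bra008037) was 5.4-fold higher (lower bound 2.88). The jasmonate O-methyltransferase gene Bra012184, whose product makes MeJA from JA, had 1 and 11 reads, so that its interval ran from 1.67-fold to 495-fold. Reads that fit near-identical copies of these genes alike are left out of the counts, and values of single copies are uncertain to that degree. Acyl-CoA oxidase 1 (Bra040093) was at 0.917-fold (0.814 to 1.03).

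JA signalling and turnover genes had a median log2 ratio of 1.42 over 15 tested members (0.91 to 2.81), with 9 at least 2-fold higher and none 2-fold lower. The 12 tested JAZ genes, which encode repressors of JA signalling that JA itself induces, lay between 0.80 and 4.62 on the log2 scale. JAZ5 (Bra016604) was 26.9-fold higher (10.2 to 101), and the JAZ1 genes Bra031065 and Bra025713 were 11.4-fold (7.28 to 18.8) and 7.44-fold (4.84 to 11.9) higher. Of the genes for the adaptor NINJA, Bra011069 was 1.89-fold higher (1.46 to 2.46) and Bra024177 was at 0.61-fold (0.497 to 0.745). Because most members were JAZ copies, counting each list member once, with the reads of its copies summed, gave a median of 0.61. Both lists lay above all of their matched random lists (percentile 100). Allene oxide synthase and the transcription factor MYC2, named as markers beforehand, had no name match in the annotation, and neither had PR1.

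Glucosinolates are the sulphur-rich defence compounds of the cabbage family, and the indole kind is made from tryptophan. Of 4 tested indole glucosinolate genes, 3 were at least 2-fold higher, with a median log2 ratio of 1.91 and a percentile of 99.9. Besides CYP81F4, these were the sulfotransferase ST5a (Bra008132, 4.27-fold, 3.81 to 4.79) and CYP83B1 (Bra034941, 3.31-fold, 3.13 to 3.50). CYP79B2 and CYP79B3, which commit tryptophan to the pathway, are spelled differently in the annotation and were added after their values had been seen. The CYP79B2 genes Bra011821 and Bra017871 were 30.4-fold (22.1 to 43.0) and 38.4-fold (21.2 to 77.5) higher, and CYP79B3 (Bra030246) was 33.4-fold higher (16.7 to 78.3). With all added spellings the list median was 4.20. Tryptophan synthesis genes had a median of 0.70 (-0.23 to 1.73), with 4 of 10 at least 2-fold higher, among them TRP1 (Bra002119, 3.59-fold, 2.23 to 5.98), ASB1 (Bra010980, 3.35-fold, upper bound 5.54) and TSB2 (Bra019075, 2.33-fold, 1.93 to 2.83). Their percentile was 98.6 among matched lists and 95.7 among unmatched lists.

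Aliphatic glucosinolate genes, which elongate the side chain of methionine or build the glucosinolate from the product, had a median log2 ratio of 0.03 over 6 tested members (-0.46 to 2.14), close to the middle of its matched random lists (random median 0.07), and the sign of this median turned negative under TMM scaling (-0.14) and median-of-ratios scaling (-0.11). A methylthioalkylmalate synthase gene (Bra013009) was 4.47-fold higher (3.19 to 6.38) and a CYP83A1 gene (Bra016908) 2.14-fold higher (1.56 to 2.98). The far more abundant CYP83A1 gene Bra032734, with 1457 and 1345 reads, was at 0.964-fold (0.895 to 1.04). The 3-isopropylmalate dehydrogenase gene Bra008463 was at 0.726-fold (0.611 to 0.863). Aliphatic genes found under other spellings, added after their values were seen, went both ways. CYP79F1 (Bra026058) had 116 and 27 reads, 4.11-fold lower (2.69 to 6.51). Sulfotransferase 5c (Bra025668) was 3.66-fold higher (2.38 to 5.78), and the sulfotransferase 5b genes Bra027880 and Bra015938 were 5.22-fold (1.96 to 17.5) and 1.68-fold (1.09 to 2.63) higher. Of the other sulfotransferase 5b genes, Bra027623 was at 1.49-fold (0.513 to 4.62) and Bra003726 had 2 and 0 reads. With all added spellings, branched-chain aminotransferase 4 among them, the list median was 0.53. Whether the indole and aliphatic lists differ from each other was not tested.

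Glucosinolate breakdown genes were higher in 12 of 14 tested cases by at least 2-fold, with a median log2 ratio of 1.70 (1.08 to 3.74) above all matched random lists. The epithiospecifier protein gene Bra037958, whose product turns breakdown towards epithionitriles and nitriles, was 23.8-fold higher (20.2 to 28.4). Myrosinase-binding protein Bra018941 was 17.9-fold higher (15.1 to 21.3) and myrosinase-associated protein Bra037954 13.4-fold higher (11.8 to 15.2). The exception at least 2-fold lower was the epithiospecifier modifier gene Bra027359, with 1563 and 619 reads. It is named because it stood alone, after its value was seen.

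**Figure D2:**
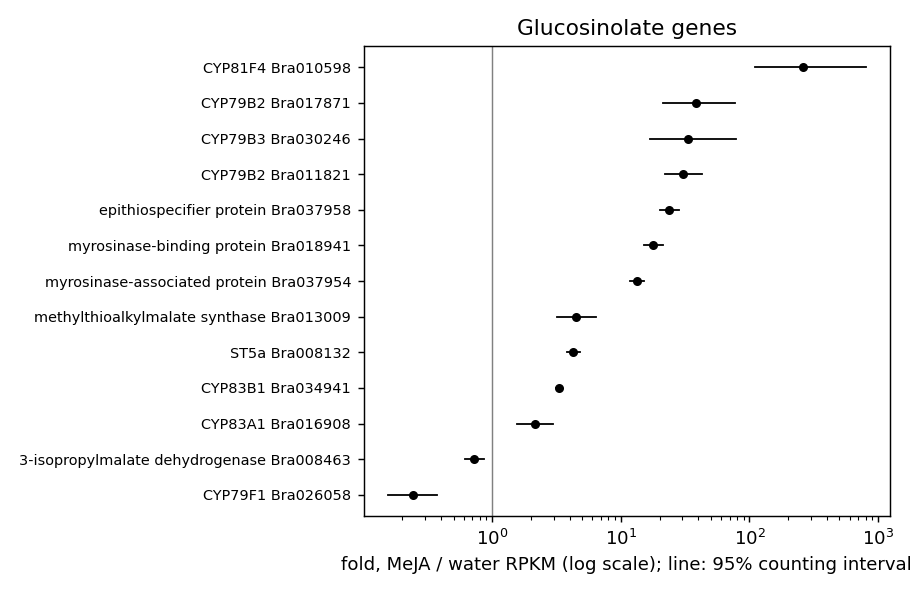
Fold of RPKM in the MeJA library over the water library (x axis, log scale) for 13 named glucosinolate genes, with points for the fold and lines for the 95% counting interval. The fold ranges from 0.243 for CYP79F1 to 260 for CYP81F4, and the CYP79B genes lie between 30.4 and 38.4. The CYP79B and CYP79F1 genes were added after their values had been seen. Other glucosinolate genes named in the text are not shown, among them sulfotransferase 5b and 5c, an abundant CYP83A1 gene and the epithiospecifier modifier gene.

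Other branches of secondary metabolism were closer to the bulk of genes. Phenylpropanoid genes had a median log2 ratio of 0.22 (-0.08 to 0.62), with 28 of 34 tested members within 2-fold and a percentile of 77.2. A cinnamate 4-hydroxylase gene (Bra021636) was 3.33-fold higher (2.40 to 4.68) and an O-methyltransferase gene similar to caffeic acid O-methyltransferase (Bra025874) 4.25-fold higher (2.34 to 8.27), while CAD6 (Bra011798) had 7 and 1 reads. Flavonoid and anthocyanin genes had a median of -0.27 (-0.48 to -0.08) with 15 of 18 within 2-fold and a percentile of 5.43. Ontology terms looked at after the values were seen had positive medians, so the sign depends on the gene set. Anthocyanin biosynthetic process had 0.35 over 16 genes (-0.43 to 1.21), with 6 at least 2-fold higher and 1 lower. Flavonoid biosynthetic process had 0.25 over 38 genes (-0.20 to 0.73), with 8 at least 2-fold higher and 4 lower. A chalcone-flavanone isomerase gene (Bra007142) was 3.35-fold lower (1.89 to 6.26), and flavonol synthase FLS3 (Bra029212) was 2.13-fold higher (1.32 to 3.51). Flavanone 3-hydroxylase (Bra007813) had 10 and 20 reads. Terpenoid backbone genes had a median of 0.34 over 8 members, with a hydroxymethylglutaryl-CoA reductase gene (Bra015739) 2.40-fold lower (2.19 to 2.63). Glutathione transferases had a median of 0.21 over 25 members, and the member farthest from 0, Bra018386, had 2 and 12 reads.

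Genes of primary leaf functions split. All 55 light-harvesting and photosystem genes lay within 2-fold, with a median of -0.01 that was -0.19 under TMM scaling. This median lay at percentile 96.9 of its matched random lists, which centred on -0.29. Those lists could draw the ribosomal protein genes, which were lower, so the percentile may be raised. The member farthest from 0, PsbP-like protein 2 (Bra005037), was 1.92-fold higher (1.70 to 2.17). Among genes of senescence and chlorophyll breakdown, with 3 tested members and a median of 1.42, chlorophyllase 1 (Bra025756), which removes the phytol tail of chlorophyll, was 28.8-fold higher (22.9 to 36.6). Abscisate and water deficit genes had a median of 3.45 over 4 members, or 2.67 with genes without reads set to 3 reads. The median rests on the adjacent genes Bra007825 (3.41) and Bra007826 (3.49), named after their values were seen. Both are annotated as the carotenoid cleavage dioxygenase CCD1 and, in the same entry, as 9-cis-epoxycarotenoid dioxygenase. Their part in abscisate synthesis was not checked, so the median is not read as an abscisate response. Reads that fit both copies alike are left out of their counts. The other members were Bra033350, at 1.17, and LEA14. LEA14 (Bra030494) had 0 reads in the water library and 11 in the MeJA library, at least 3.83-fold higher against a floor of 3 reads, with a counting interval that began at 2.62-fold. Salicylate response genes had a median of 0.47 over 11 members at the 85.8th percentile, and their member farthest from 0, a PAD4 gene (Bra033432), had 0 and 5 reads. Ethylene genes had a median of 0.53 over 12 members at the 93.8th percentile, with an ethylene receptor gene (Bra023756) 4.81-fold higher (1.79 to 16.2).

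Ribosomal protein genes had a median log2 ratio of -1.30 over 367 tested members (-1.36 to -1.22), and 250 of them were at least 2-fold lower against 6 at least 2-fold higher. The median lay below all matched random lists, of which the lowest was at -0.27. The 238 members annotated as 40S, 60S or cytosolic had a median of -1.43 (-1.53 to -1.37), and the 23 annotated as 30S, 50S, plastid or mitochondrial had a median of -0.37 (-0.70 to 0.10). The member farthest from 0, a ribosomal protein L11 family gene (Bra017714), had 5 and 0 reads. Genes of cell division, mostly histones, had a median of -1.06 over 18 members (-1.42 to -0.58), with 10 at least 2-fold lower and none higher, and histone H2B-like Bra020275 was 3.95-fold lower (1.79 to 9.90). Among housekeeping genes the median was -0.87 over 22 members, with 8 at least 2-fold lower. The beta-1 tubulin gene Bra015815 had 3845 and 1284 reads, 2.87-fold lower (2.69 to 3.06). These 3 lists kept negative medians under each scaling tried. Short genes were lower as a class: with genes sorted by coding length into 4 classes of equal size, the median log2 ratio was -0.26 in the shortest class (median 462 bases) and 0.48 in the longest (2169 bases). Ribosomal protein genes had a median coding length of 495 bases, and without them the median of the shortest class was -0.20.

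**Figure D3:**
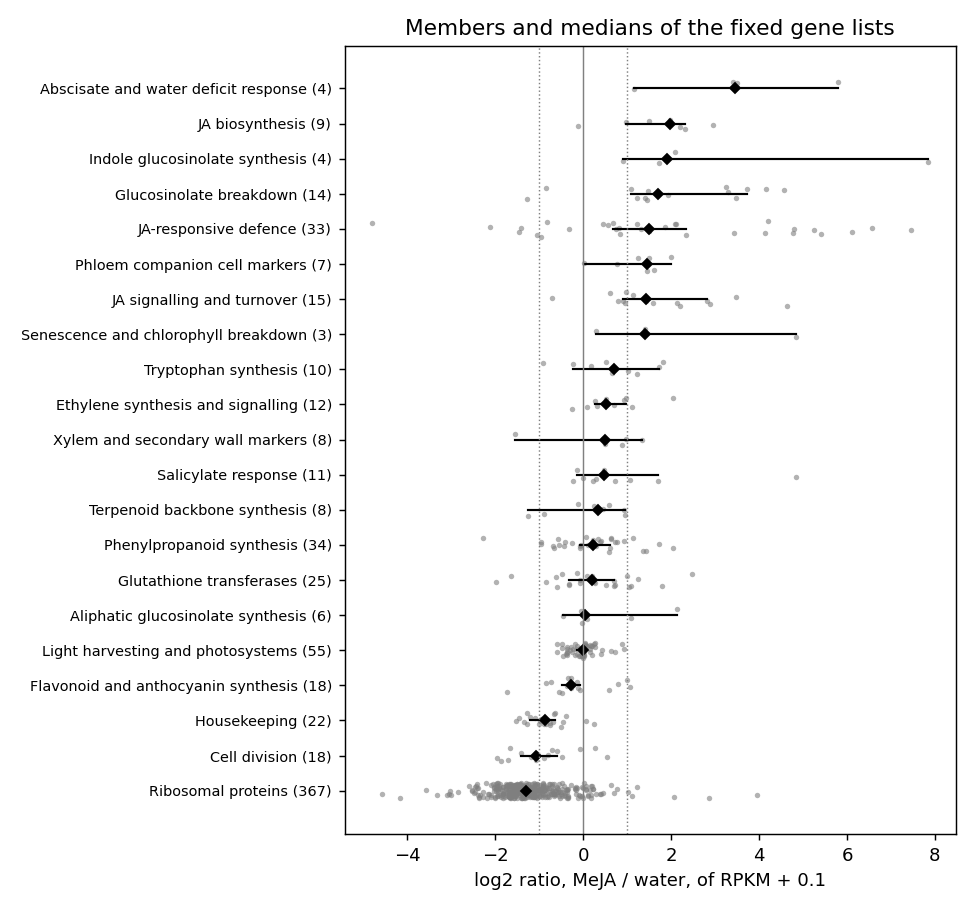
Log2 ratio of RPKM plus 0.1, MeJA over water (x axis), of each tested member (grey points) of the 21 gene lists with at least 3 tested members (y axis, number of members in brackets), with the list median (black diamond) and its 95% interval over members, or the full range in the smallest lists. Dotted lines mark 2-fold differences, and medians run from -1.30 for ribosomal proteins to 3.45 for the 4 abscisate and water deficit genes, where the middle values are those of adjacent CCD1 copies.

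Markers of leaf cell types and of other organs were measured beside these groups. Phloem companion cell markers had a median of 1.46 over 7 genes (0.02 to 1.99) at the 99.97th percentile, with 5 at least 2-fold higher and 2 in between. Other phloem protein 2 genes and the sucrose transporter gene SUT2 were removed from this list after values had been seen. With them left in, the median stayed within this wide interval, which reaches down to 0.02, and no percentile was computed. The lower end of that interval lies below 0 after the TMM shift. APL (Bra035118) was 4.18-fold higher (1.78 to 11.3). Xylem and secondary wall markers had a median of 0.51 over 8 genes at the 79.3th percentile, and IRX9 (Bra005218) had 7 and 2 reads. The 2 tested myrosin cell markers, both also in the glucosinolate breakdown list, had a median of 0.13, with myrosinase 2 (Bra020523) 2.12-fold higher (1.64 to 2.76) and myrosinase 1 (Bra020551) at 2 and 1 reads. The 2 flower and pollen markers, both pollen coat protein genes, had a median of -0.91, and Bra015779 had 752 RPKM in the water library and 397 RPKM in the MeJA library. After the removals, the trichome, guard cell, root and shoot meristem lists had no tested member.

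Among 706 gene ontology terms with 10 to 300 tested genes, the highest medians belonged to phospholipid transporter activity (1.21 over 12 genes), dioxygenase-type oxidoreductase activity on single donors (1.19 over 26), glucosinolate biosynthetic process (1.14 over 12), glycine catabolic process (1.12 over 10) and indole phytoalexin biosynthetic process (1.10 over 15). Each lay at or above the 99.8th percentile of matched random lists, which in part restates that they were picked as the 5 highest of 706. The lowest medians belonged to the small ribosomal subunit (-1.41 over 146), the large ribosomal subunit (-1.38 over 215), ribonucleoprotein complex biogenesis (-1.16 over 166), fluid transport (-0.95 over 20) and phosphoprotein binding (-0.84 over 15). Terms that name JA, wounding or glucosinolates were also looked at, after the values were seen. Jasmonic acid metabolic process had a median of 0.72 over 30 genes at percentile 99.98. Jasmonic acid mediated signaling pathway had a median of 0.29 over 13 genes, with 1 at least 2-fold higher, at percentile 72.6. The JAZ5 and JAZ1 genes named above do not carry this term in the deposited annotation, so its median does not cover them. Response to wounding had a median of 0.44 over 19 genes at percentile 86.8, and glucosinolate catabolic process 0.63 over 11 genes at percentile 94.2.

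Depth limits what can be said of single genes. In 100 simulated draws without any difference, counting error alone placed a median of 743.5 genes (667 to 813) at least 2-fold higher and 760 (710 to 816) at least 2-fold lower. Among the 9898 genes with 100 or more reads over both libraries, where such draws gave 0 to 3 genes in either direction, 992 were at least 2-fold higher and 847 at least 2-fold lower. The whole counting interval lay beyond 2-fold for 632 higher and 513 lower genes. The median log2 ratio of all tested genes was 0.17, and TMM scaling shifted every ratio by -0.18, which turned the split of 59.9% higher among all 2-fold calls into 46.5%.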

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

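The percent of a gene covered by reads, a deposited column that the comparison does not use, was compared after the other results were seen. Over 1780 genes with 20 to 200 water reads and MeJA reads within 10% of that number, the median of the per-gene differences, MeJA minus water, was 0.315 percentage points (0.07 to 0.62 over genes), which is what marked it for a closer look. The medians of the libraries over the same genes ran the other way, at 80.1% in the water library and 79.8% in the MeJA library. Over the 182 genes with equal read numbers the difference was 0.09 (-1.03 to 0.91), and this closer match was tried only after the first.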

How the results depend on the processing

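No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The length settings, the setting that keeps matches to other proteins and the added spellings were chosen after seeing the data. Counts moved by over 1.5 times under stricter rules, which by construction keep fewer genes: 1918 higher and 1537 lower at 5 RPKM or more, 871 and 510 at 4-fold, 632 and 513 with the counting interval beyond 2-fold, and 2314 higher with a pseudocount of 1. With the median of each of 10 coding length classes set to 0 they were 2844 and 2512. Of 252 list medians under alternatives, 243 stayed within the interval over members. Ribosomal proteins left theirs, with medians of -1.47 under TMM, -1.44 under median-of-ratios, -1.07 with the length medians set to 0 and -1.21 per list member. Light harvesting gave -0.19 under TMM, -0.15 under median-of-ratios and 0.052 with length medians set to 0. JA signalling and turnover gave 0.61 per list member, since its JAZ copies then count once, and JA-responsive defence 0.37 with matches to other proteins left in. For the remaining shifts the cause was not tested beyond the setting itself. Added spellings moved the indole glucosinolate median to 4.20, inside its wide interval. Of 42 list percentiles, 40 stayed inside or outside the central 95% of random lists. Tryptophan synthesis went to 95.7 among unmatched lists. Light harvesting went to 99.5 among length-matched lists, which could also draw the ribosomal protein genes. Among the 52 genes named by the rule and the 10 highest and lowest ontology terms, none reversed. Of 260 single-gene values, 15 left their counting interval without changing sign, and 2 of 20 term medians were scored as moved. Genes and terms added later were not run under the alternatives one by one. Genes with few reads, such as those of 0 to 10 in a library, carry intervals too wide to rank.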

Other observations

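All families in this paragraph were picked after the values had been seen. WRKY transcription factors, a family with many defence regulators, had a median log2 ratio of 0.998 over 52 tested genes (0.61 to 1.38), with 26 at least 2-fold higher and 1 lower, and 0.83 under TMM scaling. Sulphur assimilation genes had a median of 0.95 over 7 genes (-0.22 to 3.37); an APS reductase gene (Bra013579) was 10.5-fold higher (7.40 to 15.5) and an APS kinase gene (Bra011822) 7.57-fold higher (2.66 to 29.7), while an ATP sulfurylase gene (Bra001891) was at 0.859-fold (0.78 to 0.947). Aquaporins had a median of -0.93 over 18 genes (-1.11 to -0.50), with 7 at least 2-fold lower and 1 at least 2-fold higher (Bra023103, 2.36-fold, 2.04 to 2.73). Medians were -0.30 over 16 xyloglucan endotransglucosylases, -0.13 over 20 expansins and -0.65 over 7 heat shock cognate 70 genes. These medians did not stand apart from matched random lists, at percentiles of 13.2, 11.9 and 12.9. Single members did differ: 5 xyloglucan endotransglucosylases were at least 2-fold lower and 3 at least 2-fold higher, and 2 expansins went each way.

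All of the tests that follow were chosen after the gene values had been seen; those on coding length and on neighbouring genes were set down before their own outcome was known, those on read uptake and on the clock genes after. The lower ribosomal protein genes were set against 3 explanations. If reads taken up by the induced genes had pressed all others down, median-of-ratios scaling would bring the median near 0, but it was -1.44. The lowest matched random list was at -0.415 on that scale. This scaling moves all genes by nearly the same log2 step, -0.145, so it could only lower the median and cannot decide the question. On the deposited scale the ribosomal median, -1.30, lay below the lowest matched list, -0.27. The fall was thus not shared alike by genes of similar expression. Genes at least 4-fold higher took 0.908% of the reads in the water library and 6.82% in the MeJA library. Short coding length accounts for part at most: lists matched on length and expression had a median of -0.36, and the ribosomal median lay lower still, a difference of -0.943. Those lists were drawn from all tested genes, ribosomal protein genes among them. The -0.36 may thus hold some of the ribosomal fall itself, and the share due to length is not resolved. Plants or leaves that differed for reasons other than the spray cannot be told apart from the spray, with 1 library per group. An effect of the hormone on ribosome synthesis may also hold, untested.

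Neighbouring genes were higher together more often than in most shuffles: 47 adjacent pairs were both at least 4-fold higher, against a median of 27 and a highest of 48 in 10000 shuffles. Some of these pairs skip gene identifiers, such as Bra017700 and Bra017703, so adjacent pairs need not be immediate neighbours. Pairs with related protein matches accounted for 11, against at most 5 in the shuffles, such as the Kunitz-type inhibitor genes Bra008024 and Bra008025. Pairs with unrelated matches numbered 5, against a shuffle median of 6. Pairs with a match classed as vague on either side numbered 31, against a shuffle median of 21 and a highest of 40. Part of the excess thus lies in pairs that were not assigned. Some of them have the same match on both sides, such as the RWP-RK domain genes Bra000307 and Bra000308, and may be related copies. Unique counting leaves out reads that fit such copies alike. Reads placed on the wrong copy and shared regulation of tandem copies both stay open.

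Among 9 tested pseudo-response regulator genes of the circadian clock the median log2 ratio was 1.31 (0.57 to 3.35), with 5 at least 2-fold higher and none lower, among them PRR7b (Bra009565, 2.49-fold, 2.06 to 3.01), PRR1b (Bra035933, 3.55-fold, 1.26 to 12.3) and the 3 genes annotated as PRR5, with 15 reads in the water library and 191 in the MeJA library. Reads moved between the PRR5 copies would raise some at the cost of others, but each of the 3 was higher and their summed reads were 13.3-fold higher (lower bound 7.86), values that were known when the test was chosen; exchange with genes not annotated as PRR5 was not tested. A later time of day at harvest of the MeJA plants would raise such day and evening genes and lower the dawn genes LHY and CCA1, but CCA1 (Bra004503) was 1.60-fold higher (1.44 to 1.78) and the LHY genes 1.18-fold (1.04 to 1.33) and 1.16-fold (1.05 to 1.28) higher. The median log2 ratio of these 3 dawn genes was 0.238, and stayed above 0 under median-of-ratios (0.09) and TMM scaling (0.06). With 3 genes, and LHY intervals that reach below equality under TMM scaling, the harvest time and the spray cannot be told apart here.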
